A study of Homo sapiens with 18 samples.

How the data were processed

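RNA sequencing of LNCaP cells was analysed from per-gene tables. RNA was taken with a column kit and made into stranded libraries, per the labels. The submitters' processing notes name FastQC, Trimmomatic, kallisto and DESeq2 and the GRCh38 genome, and the versions of these tools are not given in the sources used here. The deposited tables hold estimated counts per gene, and further deposited tables hold, for each gene and each of 164776 transcripts, an estimated count, a TPM value (transcripts per 1000000) and another number joined by slashes. That last number carries no name in the tables and was not used. The names of the count tables mention TPM, but their values matched the estimated counts of the joined tables within 0.00005, and the TPM values of a library summed to 1000000, so each was used in the unit its values show. Counts came already summed per gene, whereas the plan had allowed for transcripts. There were 4 files, with 34912 genes, of which 34846 were found in GENCODE v29; 27 gene symbols were stored as dates, and genes were therefore joined by identifier.

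Samples were grouped by siRNA (control, KLF5, NFYA) and treatment (vehicle, R1881) from their labels, 3 per group, and replicate numbers are only names in label order. The sample with label number 7, siKLF5 vehicle replicate 1, has no column in the tables and was not used here. No paired analysis was possible because each label number belongs to 1 library only. The tables cover control with siNFYA (12 libraries) and control with siKLF5 (11 libraries), with identical control columns, and each was fitted separately. Each library counted as a sample. Libraries of a group differed by more than counting error, which does not show that they were separate cultures. Library totals ran from 4416653 to 6872421 estimated counts, so that 3 counts over a group of 3 stand for about 0.2 CPM (counts per 1000000); intervals and floors given for low counts cover counting error alone.

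Counts were rounded to whole numbers, scaled by TMM, filtered with filterByExpr, and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with a coefficient for each group and contrasts for 9 comparisons: R1881 against vehicle under each siRNA, each knockdown against control siRNA in each treatment, and the 2 interactions of knockdown with R1881. P-values were adjusted by Benjamini and Hochberg, and a gene passed at adjusted p under 0.05. The filter left 12601 genes in the control and siNFYA table and 12733 in the control and siKLF5 table. Log2 fold changes come with a standard error worked out from the change and its F statistic. Where a group is near 0 counts it can be too small, so none is given for STEAP4 and SI. CPM computed from the deposited estimated counts were scaled within each table for named genes, and over all 17 libraries together for the knockdown check and its plot, so the same gene can differ slightly between them. Where a group had no counts, the fold is given as a lower bound against 3 counts over the group, and with 1 to 3 counts as a ratio with a 95% counting interval. Exact binomial intervals for single libraries were computed with SciPy 1.17.1, tables with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.

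Lists of genes were written down before the data were examined, as were the groups, the comparisons, the tests and the alternatives not named below as added. The 31 lists were androgen-induced genes, androgen-repressed genes, cholesterol synthesis, fatty acid synthesis and desaturation, fatty acid oxidation, glycolysis, tricarboxylic acid cycle, oxidative phosphorylation (nuclear-encoded subunits), mitochondrially encoded mRNAs, pentose phosphate pathway, serine, glycine and one-carbon metabolism, ATF4 amino acid response, polyamine metabolism, purine and pyrimidine synthesis, hexosamine pathway and glycosylation, G2/M cell cycle, DNA replication and S phase, p53 target genes, endoplasmic reticulum stress and chaperones, heat shock proteins, interferon response, hypoxia response, NF-Y subunits, KLF and SP family, luminal, basal, neuroendocrine and neuronal, stromal and mesenchymal, and blood and endothelial markers, immediate early genes, and cytosolic ribosomal proteins. They hold 818 genes, 36 of them in more than 1 list. Each list with at least 3 measured members was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over lists, and again with a correlation estimated from the list. Members were also counted with p-values adjusted over the list alone.

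Genes are named by a rule. For each comparison with control libraries it takes the 6 largest rises and 6 largest falls among genes that passed. Such a gene must be protein-coding and also carry a symbol that is not a clone-type label. It must have a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. Genes of the Y chromosome and XIST are left out. The rule adds, per list past camera, the 3 members with the smallest adjusted p in the direction of the list and 1 in the other direction. In each comparison the rule also adds the targeted gene, KLK3, TMPRSS2 and FKBP5. Some genes that the rule names are not reported here. For interactions the rule takes 5 genes per direction by adjusted p. NFYB, NFYC, the genes shared between lists and the genes called in opposite directions by the siRNAs were named outside it. Some named genes share reads with near-identical copies or with the parts of a readthrough transcript, so that their estimated counts are uncertain: GOLGA8A, GOLGA8B, NPIPA7, NPIPB4, RGPD5, CBS, CBSL, SLX1B, GAGE12G, SMIM11A, ARHGEF35, PCDH11X, PCDHGA5, UGT2B11, UGT2B15, UGT2B17, BLOC1S5-TXNDC5, JMJD7-PLA2G4B and ATP6V1G2-DDX39B.

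Shared calls of siKLF5 and siNFYA were counted over 12554 genes tested in both. The covariance of their log2 fold changes was set beside 20 simulations of unchanged groups against the same controls. Alternatives were size factors of DESeq2, the Wald test of DESeq2 1.42.0, no filter, a minimum of 5 CPM in 3 libraries, a fit of the compared groups alone, adjusted p under 0.01, limma-trend on log2(TPM + 1), all libraries in a single fit, the control columns of the other table, and leaving out each library in turn. Added after seeing the data were scaling by library totals, removal of mitochondrial and rRNA-like genes before scaling, the direct comparison of siNFYA with siKLF5, the comparison of each siRNA with its own control libraries (1 control for an siRNA and the other controls for the other, in 6 assignments, with 20 simulations), and splits of the samples balanced over the arms. The steps were tested on simulated data with 200 changed genes. The edgeR test recovered 66% of 1.5-fold, 88% of 2-fold and 96% of 4-fold changes for siNFYA in vehicle, 66, 78 and 94% for siKLF5 in vehicle, and 54, 76 and 94% for the siNFYA interaction, and between 4.58 and 10.5% of its calls were false, against 0 to 4.20% with DESeq2.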

Results

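The experiment asked how the transcription factors KLF5 and NFYA shape the androgen response and the metabolism of LNCaP cells, a prostate cancer line that responds to androgen. NFYA is the subunit of the CCAAT-binding factor NF-Y that contacts DNA, and KLF5 is a zinc-finger factor of the KLF family. Cells received siRNA pools against KLF5 or NFYA or a control siRNA, were kept in steroid-depleted serum (5% charcoal-stripped, 48 h), and were given the synthetic androgen R1881 (10 nM) or vehicle (96% ethanol) for 24 h. The labels describe 6 groups of 3 samples, and 17 of the 18 samples were analysed here, with siKLF5 vehicle replicate 1 not analysed here, so that this group has n = 2. Library totals, by replicate, were 6174633, 6411869 and 6209940 estimated counts (control vehicle), 5759057, 5776649 and 5581124 (control R1881), 6872421 and 6661047 (siKLF5 vehicle, replicates 2 and 3), 5380779, 5737908 and 4582804 (siKLF5 R1881), 5123967, 5336700 and 4416653 (siNFYA vehicle), and 5583076, 6047263 and 5034642 (siNFYA R1881). Libraries of a group differed by more than counting error in 16 of 16 pairs (chi-square per degree of freedom 1.30 to 14.5). The highest values, 10.8 and 14.5, were in pairs with siNFYA vehicle replicate 3. That library held 125925 counts of the rRNA-like gene AC010970.1, against 6385 in replicate 2. Nothing in the labels says that replicates were separate cultures, so p-values here measure the spread between these samples. The leading principal component held 72.6% of the variance and parted R1881 from vehicle, and the next held 4.22%.

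The libraries also differed in make-up. Mitochondrially encoded transcripts held 1.89 ± 0.156% of counts in control vehicle and 1.38 ± 0.0543% in control R1881 (mean ± SD, n = 3), against 2.71 ± 0.355% (n = 2) and 2.49 ± 0.313% (n = 3) with siKLF5 and 2.81 ± 0.206% and 2.57 ± 0.0384% (n = 3) with siNFYA. Transcripts annotated as retained introns held 2.18 and 1.96% in the control groups, 2.59 and 2.34% with siKLF5, and 2.87 and 2.62% with siNFYA, in the same order of treatments. The genes GOLGA8A and GOLGA8B, golgin copies on chromosome 15, and the poly(A)-binding protein gene PABPC1L rose together with these shares in the knockdown groups. The rRNA-like gene AC010970.1 took 2.85% of the counts of siNFYA vehicle replicate 3 (95% counting interval 2.84 to 2.87%) and 0.0902 to 0.424% elsewhere.

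**Figure D1:**
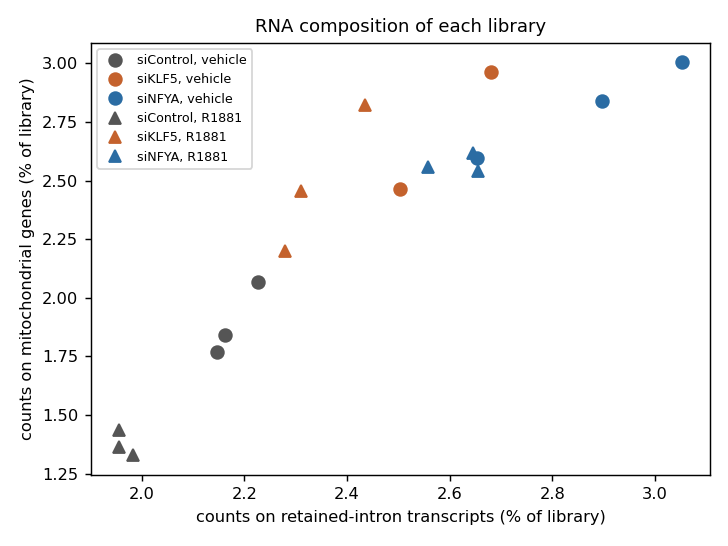
Share of counts on mitochondrially encoded genes (y axis, % of the library) against the share on transcripts annotated as retained introns (x axis, %), with 1 point per library, circles for vehicle, triangles for R1881 and a colour per siRNA. Control R1881 libraries averaged 1.38% mitochondrial and 1.96% retained-intron counts, and siNFYA vehicle libraries 2.81 and 2.87%.

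Knockdown was checked at the targeted genes. NFYA (ENSG00000001167, chr6:41072945-41099976, GRCh38) fell from 70.9 ± 2.48 to 46.2 ± 2.01 CPM (counts per 1000000) in vehicle (log2 -0.62, SE 0.0631, adjusted p = 4.06e-07) and from 86.9 ± 2.61 to 56.4 ± 2.59 CPM in R1881 (log2 -0.62, SE 0.0615, adjusted p = 2.37e-07; n = 3 each), so that most NFYA transcript was still present. The other NF-Y subunits NFYB and NFYC did not pass with siNFYA (adjusted p = 0.946 and 0.647 in vehicle, 0.396 and 0.237 in R1881). KLF5 (ENSG00000102554, chr13:73054976-73077542) fell with siKLF5 in R1881 from 28.4 ± 3.34 to 12.8 ± 2.07 CPM (n = 3 each; log2 -1.15, SE 0.163, adjusted p = 0.000228), a call lost in the TPM fit (-0.14). In vehicle KLF5 was scarce, with 33, 30 and 22 counts in the control libraries, and its lower level with siKLF5 did not pass (log2 -1.08, SE 0.346, adjusted p = 0.149), except when no filter was used (-1.09). There siKLF5 replicate 2 held 7 counts (1.02 per 1000000, 95% counting interval 0.410 to 2.10) and replicate 3 held 22 (3.30, 2.07 to 5.00), so the library labelled siKLF5 vehicle replicate 3 did not show a clearly lower KLF5 level than the controls. Leaving out replicate 3 gave KLF5 a log2 change of -2.14, and leaving out replicate 2 gave -0.46. NFYA did not pass with siKLF5 (adjusted p = 0.869 and 0.938), nor KLF5 with siNFYA (0.999 and 0.753).

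**Figure D2:**
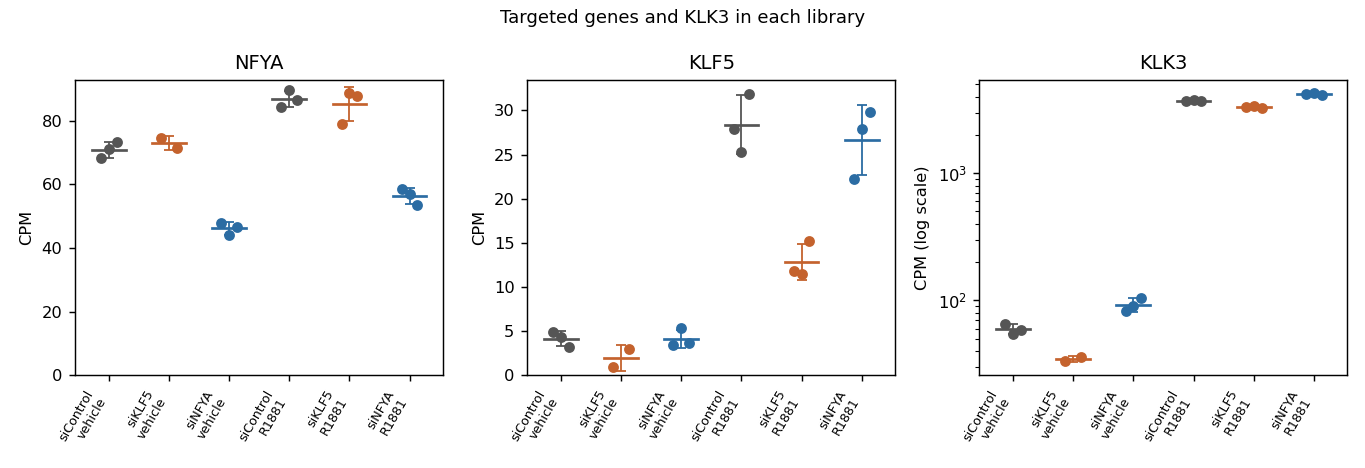
Level of NFYA, KLF5 and KLK3 (y axis, CPM, logarithmic for KLK3) in the 6 groups, with 1 point per library, a line at the mean and a bar for the SD. NFYA stands at 70.9 CPM in control vehicle and 46.2 in siNFYA vehicle, and KLF5 at 28.4 CPM in control R1881 and 12.8 in siKLF5 R1881.

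R1881 against vehicle in control siRNA showed which transcripts respond to androgen. KLK3 (ENSG00000142515, chr19:50854915-50860764), which encodes prostate-specific antigen, rose from 59.6 ± 5.56 to 3729 ± 66.3 CPM (n = 3 each; log2 5.97, SE 0.0633, adjusted p = 6.05e-29). FKBP5, a co-chaperone of steroid receptors, rose with log2 5.31, the membrane protease TMPRSS2 with 4.75 and the stress-responsive NDRG1 with 5.50. Among the targeted factors KLF5 rose with log2 2.76 (SE 0.164, adjusted p = 1.64e-13) and NFYA with 0.29 (SE 0.0562, adjusted p = 8.05e-05), while NFYB fell (-0.25, SE 0.0831, adjusted p = 0.0105) and NFYC did not pass (adjusted p = 0.662). Under library totals, a scaling added after seeing the data, NFYA was at 0.05 and did not pass (adjusted p = 0.409), KLF5 was at 2.52 and NFYB at -0.49, and NFYC passed at -0.20 (adjusted p = 0.0239). The largest rises under the naming rule included the secreted acute-phase protein ORM1 (24.0 ± 2.02 CPM from no counts, at least 163-fold). The metalloreductase STEAP4 rose with log2 9.76 (275 ± 16.6 from 0.289 ± 0.379 CPM). The other rises were in the protease precursor PGC (ratio 523, 95% counting interval 93.3 to 20700), the transcriptional repressor SNAI2 (369, 65.6 to 14600), CCDC141 (346, 95.3 to 2860) and the anion exchanger SLC26A3 (at least 38.8-fold). The largest falls included the cholesterol exporter ABCA1 (at least 34.5-fold lower) and the readthrough transcript BLOC1S5-TXNDC5 (at least 27.6-fold lower). The disaccharidase SI fell with log2 -6.35 (38.0 to 0.443 CPM). The other falls were in the protocadherin PCDH11X (85.6-fold lower, 29 to 417), the adhesion protein AMIGO2 (74.5-fold lower, 25.2 to 363) and the death-associated kinase DAPK1 (60.7-fold lower, 16.5 to 505).

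Lists of known function placed these changes. Beside each list median stands the camera adjusted p, followed where given by that with an estimated correlation. Of 74 measured androgen-induced genes 72 rose and 1 fell (median log2 2.62, camera adjusted p = 1.77e-41, and 0.00354 with an estimated correlation). The exception, the prostatic acid phosphatase ACPP, fell with log2 -0.18 (adjusted p = 0.00198). Of 17 androgen-repressed genes 13 fell and 4 rose (median -1.85, adjusted p = 6.26e-06 and 0.00527). Falls were in the cholinesterase BCHE (-3.15), the kinase inhibitor CAMK2N1 (-3.62) and the decarboxylase DDC (-3.45), and a rise was in the steroid-conjugating UGT2B11 (2.68). In cholesterol synthesis 22 of 24 genes rose and 1 fell (median 0.636, adjusted p = 1.06e-10 and 0.0037). The rises included HMGCS1 (1.57), while TM7SF2 fell (-0.49). In fatty acid synthesis and desaturation 17 of 25 rose and 7 fell (median 0.459, adjusted p = 0.00101 and 0.0352). Rises included the acyl-CoA synthetase ACSL3 (3.44; 2213 against 205 CPM) and the elongases ELOVL7 (4.14) and ELOVL5 (2.15), while ELOVL6 fell (-1.03). The androgen-induced list shares IDI1, HMGCS1 and INSIG1, among others, with the cholesterol list and ELOVL5, ACSL3, FADS1 and SCD with the fatty acid list. All 15 hexosamine pathway and glycosylation genes changed, 14 of them upward (median 1.33, adjusted p = 2.24e-09 and 0.00354). Rises were in the sialyltransferase ST6GALNAC1 (6.35), UAP1 (2.84) and PGM3 (1.84), against a fall in OGT (-0.37). All 27 genes of endoplasmic reticulum stress and chaperones rose (median 1.15, adjusted p = 4.40e-18 and 0.00527), among them ERN1 (2.71), HERPUD1 (2.24) and DNAJC3 (1.93). The ATF4 amino acid response had 20 of 25 genes higher and 1 lower (median 0.729, adjusted p = 3.07e-09 and 0.0386). Rises were in the amino acid carriers SLC1A5 (1.80) and SLC38A2 (1.35) and in PCK2 (1.05), and a fall in SLC7A5 (-0.86). In polyamine metabolism 8 of 12 rose and 1 fell (median 0.596, adjusted p = 0.00161). These included ornithine decarboxylase ODC1 (3.17; 4255 against 474 CPM), SAT1 (3.46) and SMS (2.94), with AZIN1 lower (-0.22). The call was lost at adjusted p = 0.0785 with an estimated correlation. Luminal epithelial markers had 16 of 22 higher and 5 lower (median 0.476, adjusted p = 0.00155 and 0.0278). Rises were in the keratins KRT8 (3.17) and KRT18 (2.72), and a fall in GATA2 (-0.99).

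Genes of cell division moved the other way. In DNA replication and S phase all 40 genes fell (median -1.60, camera adjusted p = 1.03e-18, and 0.0076 with an estimated correlation), including the helicase subunits MCM4 (-1.93) and MCM3 (-1.90) and the sliding clamp PCNA (-1.50). In G2/M cell cycle 39 of 40 fell and none rose (median -0.991, adjusted p = 4.11e-16 and 0.00715), among them TOP2A (-1.47), BUB1B (-1.67) and CDK1 (-1.08). Purine and pyrimidine synthesis had 14 of 25 lower and 3 higher (median -0.308, adjusted p = 0.00206 and 0.0339). Falls were in TYMS (-1.73), RRM2 (-1.68) and IMPDH2 (-0.67) and a rise in IMPDH1 (1.42). RRM1, RRM2 and TYMS are also in the replication list. Of 27 p53 target genes 16 fell and 4 rose (median -0.456, adjusted p = 0.0269). Falls were in BTG2 (-2.22), TP53INP1 (-2.02) and SESN1 (-1.52) against a rise in the death receptor TNFRSF10B (1.70). The call was lost at adjusted p = 0.0604 with an estimated correlation. In the interferon response 14 of 33 fell and 5 rose, or 14 and 4 adjusted over the list alone (median -0.356, adjusted p = 0.0376). OAS3 (-1.56), DDX58 (-1.40) and TRIM25 (-0.65) were lower and ISG20 (0.98) higher. With an estimated correlation the adjusted p = 0.328. All 13 mitochondrially encoded mRNAs fell (median -0.247, adjusted p = 0.00169), among them MT-ATP6 (-0.33), MT-ND1 (-0.30) and MT-ND2 (-0.27). The call was lost at adjusted p = 0.441 with an estimated correlation. Of 73 cytosolic ribosomal proteins 32 fell and 3 rose (median -0.0738, adjusted p = 0.00193). RPS3 (-0.23), RPL13A (-0.25) and RPL5 (-0.22) were lower and RPL34 (0.14) higher. With an estimated correlation the adjusted p = 0.658, and RPL34 turned to -0.02 in the TPM fit and -0.09 under library totals.

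The remaining lists did not pass the camera test for R1881 in control siRNA, although single members changed. Central carbon metabolism was mixed. Glycolysis had 7 higher and 10 lower of 25 (median -0.067, mean 0.325, tested downward; adjusted p = 0.756), and fatty acid oxidation 9 and 9 of 23 (median -0.0914, mean 0.169, tested upward, adjusted p = 0.384). The tricarboxylic acid cycle had 11 and 4 of 28 (median 0.0453, adjusted p = 0.185), nuclear-encoded subunits of oxidative phosphorylation 17 and 4 of 52 (median 0.0417, adjusted p = 0.496), and the pentose phosphate pathway 4 and 3 of 12 (median 0.0371, adjusted p = 0.922). Serine, glycine and one-carbon metabolism had 11 and 6 of 19 (median 0.261, adjusted p = 0.269). For stress and signalling the counts were 6 and 5 of 18 heat shock proteins (median 0.0247, mean -0.0174, adjusted p = 0.922), 9 and 6 of 21 hypoxia response genes (9 and 7 over the list alone, median 0.123, adjusted p = 0.324) and 8 and 2 of 14 immediate early genes (median 0.367, adjusted p = 0.214). Of the factor families, 1 and 1 of 3 NF-Y subunits (median 0.0394, adjusted p = 0.922) and 8 and 5 of 17 KLF and SP genes (median 0.126, adjusted p = 0.503) changed. Among lineage markers, 2 and 2 of 5 basal (median -0.0136, tested upward, adjusted p = 0.747), 0 and 2 of 4 neuroendocrine and neuronal (median -0.773, adjusted p = 0.265), and 2 and 5 of 10 stromal and mesenchymal genes (median -0.43, adjusted p = 0.346) rose and fell, and of 2 measured blood and endothelial markers 1 rose and 1 fell, too few to test.

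In the test over all 12601 genes (edgeR) 7932 passed adjusted p under 0.05 for R1881 in control siRNA, 4051 higher and 3881 lower, and 2114 changed at least 2-fold, 941 higher and 1173 lower. Changes are relative to TMM scaling, under which 51.07% of the called genes were higher. Scaling by library totals put the median of all genes at -0.247, from -0.0102, and left 28.21% of the called genes higher.

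**Figure D3:**
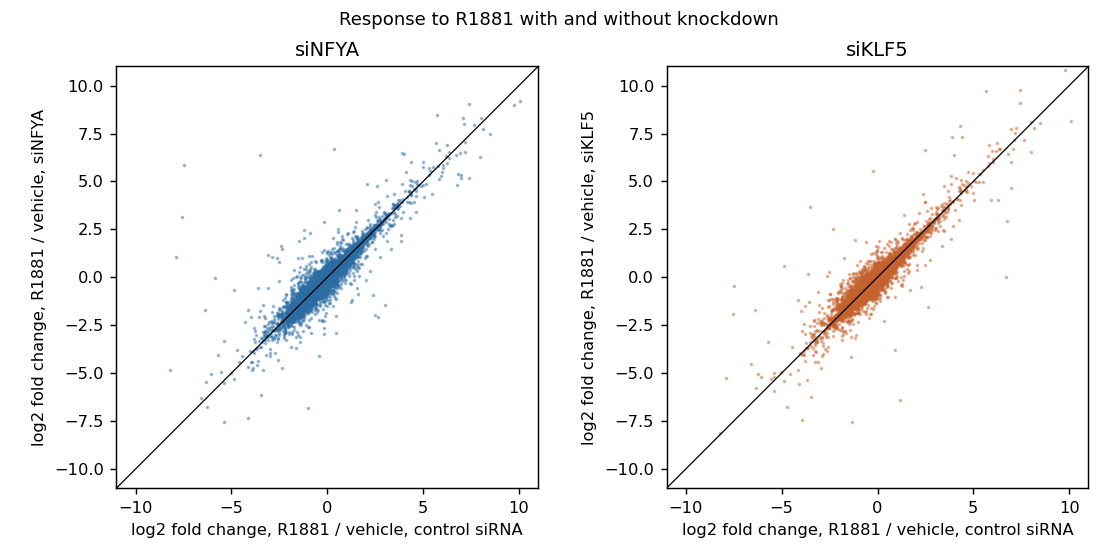
R1881 log2 fold change of each tested gene in the knockdown arm (y axis) against that in control siRNA (x axis), 1 panel per siRNA, with the line of equality. The correlation is 0.909 for siNFYA and 0.929 for siKLF5.

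The R1881 log2 changes over all genes were alike in both knockdown arms, where the targeted transcripts were at most partly lowered. With siNFYA 7828 genes passed for R1881 (3926 higher, 3902 lower), its log2 changes correlated with those in control siRNA at r = 0.909, and 6713 genes passed in both in the same direction against 16 in opposite directions. With siKLF5 7533 genes passed (3911 higher, 3622 lower), r was 0.929, and 6627 passed in the same direction against 4 in opposite directions. Androgen-induced genes had a median log2 of 2.67 with siNFYA and 2.70 with siKLF5, DNA replication and S phase -1.79 and -1.51, and the ATF4 amino acid response 0.421 and 0.678. The ATF4 call was lost in both arms, at adjusted p = 0.154 and 0.0838 with an estimated correlation. Of 30 lists tested, 14 passed in each arm, and 11 with siNFYA and 8 with siKLF5 also passed with an estimated correlation.

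With siNFYA in vehicle, mitochondrially encoded mRNAs, the ATF4 amino acid response and serine, glycine and one-carbon metabolism were higher as lists. Androgen-repressed genes were lower as a list. Asparagine synthetase ASNS rose from 189 ± 6.04 to 238 ± 1.58 CPM (n = 3 each; log2 0.34, adjusted p = 3.54e-06), the glutamine carrier SLC1A5 with 0.37 and PCK2 with 0.34. KLK3 rose from 59.6 ± 5.56 to 93.0 ± 11.4 CPM (log2 0.64, SE 0.0681, adjusted p = 7.47e-07), while FKBP5 (0.03, adjusted p = 0.809) did not pass. TMPRSS2 was lower (log2 -0.16, adjusted p = 0.0459), a call that ended in a fit of the compared groups alone and turned to 0.10 in the TPM fit. The largest falls were in the readthrough BLOC1S5-TXNDC5 (-2.67), the diamine oxidase AOC1 (-2.41; 6.04 ± 0.651 to 1.08 ± 0.646 CPM), SMIM11A (-1.60), ACTRT3 (-1.12), the growth factor VEGFB (-1.06) and the glutamate receptor GRIK1 (-0.99). The largest rises were in GAGE12G (2.56), the GTPase-activating TBC1D10C (2.14; 1.27 to 5.66 CPM), the convertase PCSK5 (2.00), the phospholipase PLCG2 (1.82), GOLGA8A (1.82) and GOLGA8B (1.77), with PCSK5 and PLCG2 carried mostly by 1 library.

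Of 30 tested lists 10 passed for siNFYA in vehicle, with the smallest adjusted p in mitochondrially encoded mRNAs and then in the ATF4 amino acid response. The ATF4 amino acid response had 18 of 25 genes higher and none lower, or 19 and 1 adjusted over the list alone (median log2 0.271, camera adjusted p = 2.87e-14, and 0.0297 with an estimated correlation). Serine, glycine and one-carbon metabolism had 7 of 19 higher and 1 lower (9 and 1 alone, median 0.149, adjusted p = 3.44e-05 and 0.0297). Rises were in CBS (0.31, uncertain because it shares reads with its copy CBSL), MAT2A (0.27) and PSAT1 (0.24). It shares PHGDH, PSAT1, MTHFD2 and ALDH1L2 with the ATF4 list. All 13 mitochondrially encoded mRNAs rose (median 0.559, adjusted p = 1.41e-30 and 0.0406), among them MT-ATP6 (0.66), MT-CO1 (0.63) and MT-ND1 (0.60). Of 17 androgen-repressed genes 8 fell and 1 rose (9 and 1 alone, median -0.159, adjusted p = 6.80e-06 and 0.0282). The opioid receptor OPRK1 (-0.75), UGT2B17 (-0.40) and DDC (-0.31) were lower and IGFBP3 (0.41) higher. Androgen-induced genes had 14 of 74 lower and 4 higher (21 and 5 alone, median -0.0957, adjusted p = 0.00327). Falls were in ACPP (-0.50), ACSL3 (-0.24) and ADAMTS1 (-0.21), but the call was lost at adjusted p = 0.333 with an estimated correlation. The remaining calls were also lost with an estimated correlation. Glycolysis had 4 of 25 higher (6 higher and 1 lower alone, ENO1 0.20, PFKL 0.19, SLC16A1 0.25, median 0.0956, adjusted p = 0.00231, then 0.0939), and purine and pyrimidine synthesis 5 of 25 higher (6 alone, APRT 0.32, PFAS 0.39, IMPDH2 0.16, median 0.089, adjusted p = 0.00454, then 0.0831). G2/M cell cycle had 5 of 40 higher (CDK1 0.24, ANLN 0.32, KIF2C 0.27, median 0.0958, adjusted p = 0.000627, then 0.202), and DNA replication and S phase 5 of 40 higher (MCM7 0.23, MCM5 0.22, E2F2 0.64, median 0.111, adjusted p = 7.44e-05, then 0.202). Luminal epithelial markers had 5 of 22 lower and 1 higher (6 and 1 alone, HOXB13 -0.18, DSP -0.22, FOXA1 -0.14 against ESRP2 0.19, median -0.0587, adjusted p = 0.0272, then 0.0939). The other 20 tested lists did not pass. Over all genes 1696 passed (841 higher, 855 lower; edgeR), with a median absolute log2 of 0.283 and 97 genes at least 2-fold changed, 83 of them higher. With size factors of DESeq2 the split was 754 higher and 1011 lower, and with the DESeq2 Wald test 390 and 566. Leaving out control vehicle replicate 2 left 1065 calls, and leaving out siNFYA vehicle replicate 1 left 1093.

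**Figure D4:**
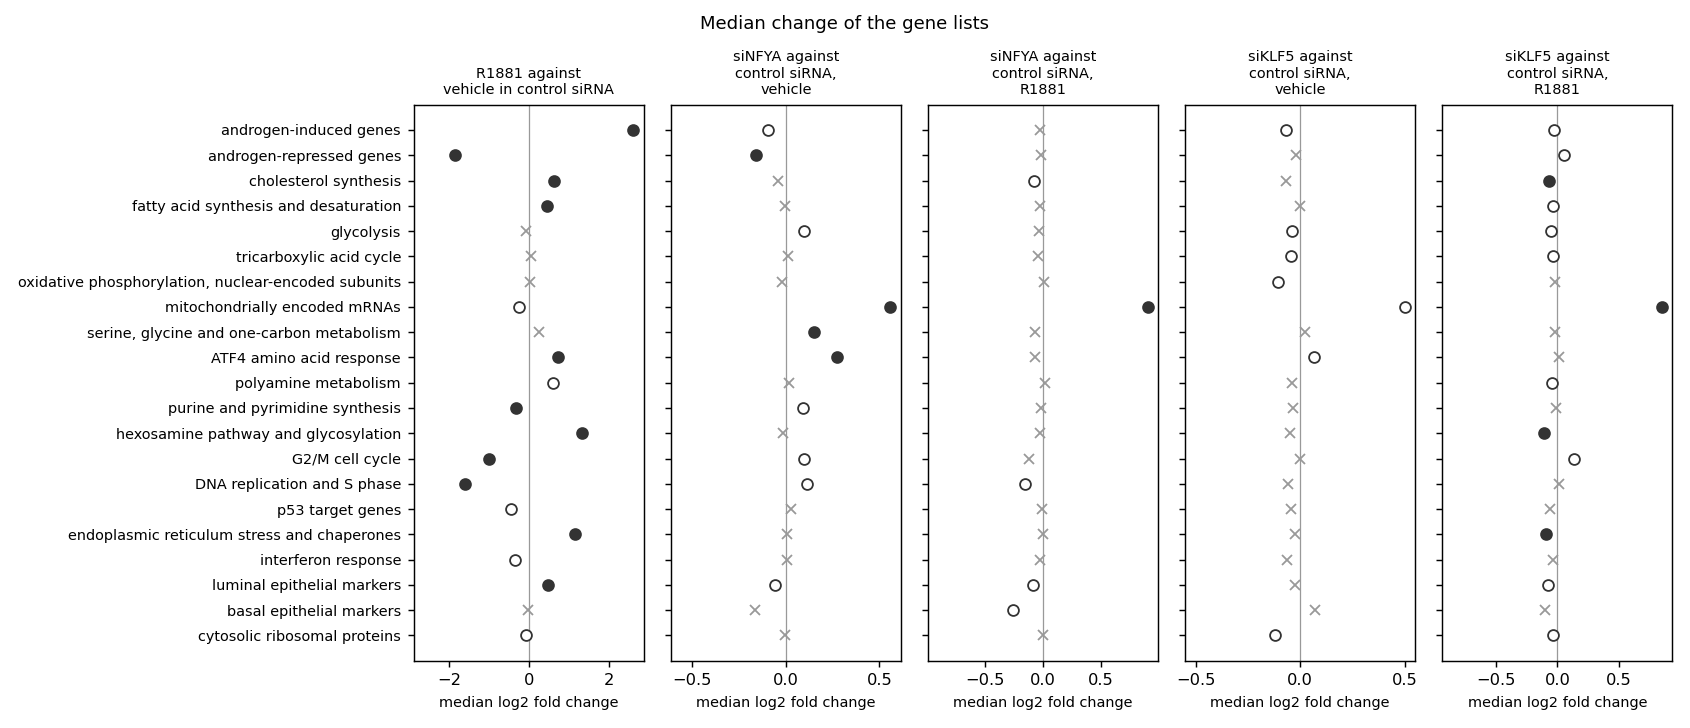
Median log2 fold change (x axis, a separate scale per panel) of 21 gene lists (y axis) in 5 comparisons, where filled marks passed camera at 0.05 with the preset and the estimated correlation, open marks with the preset alone, and grey crosses did not pass. The ATF4 amino acid response stands at 0.271 for siNFYA in vehicle, and mitochondrially encoded mRNAs at 0.903 for siNFYA in R1881.

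Mitochondrially encoded mRNAs stood further above control siRNA with siNFYA in R1881 than in vehicle, while the ATF4 list did not pass in R1881. Their share of counts was 2.81% with siNFYA in vehicle and 2.57% in R1881, against 1.89 and 1.38% in control siRNA. The siKLF5 interaction had a like median (0.361, against 0.354 with siNFYA), although its call was lost with an estimated correlation. With siNFYA in R1881 all 13 mitochondrially encoded mRNAs rose (median log2 0.903, camera adjusted p = 2.53e-63, and 0.0179 with an estimated correlation). Among them were MT-CO3 (0.94), MT-ATP6 (0.91) and MT-CO1 (0.89). The largest falls were in VEGFB (-1.04), the heparan sulfate proteoglycan GPC6 (-1.04), the phosphatase PTPRR (-1.03), the potassium channel KCNQ1 (-1.02), TTC9 (-0.97) and CAMK2N1 (-0.91; 22.7 ± 1.97 to 12.0 ± 1.55 CPM, n = 3 each, adjusted p = 4.39e-05). The largest rises were in multi-copy genes, namely CBSL (ratio 45.0, 95% counting interval 12.1 to 378), SLX1B (2.38), NPIPA7 (2.31), GOLGA8B (2.24) and GOLGA8A (1.84), and in PABPC1L (2.01). TMPRSS2 (-0.10, adjusted p = 0.106) and FKBP5 (0.04, adjusted p = 0.652) did not pass. KLK3 was higher (log2 0.17, SE 0.0476, adjusted p = 0.0313; 4201 ± 65.9 against 3729 ± 66.3 CPM), a call lost when any 1 library was left out and in the TPM fit. Cholesterol synthesis had 5 of 24 lower and none higher (9 alone, SREBF2 -0.17, TM7SF2 -0.23, median -0.0806, adjusted p = 0.00281), and luminal epithelial markers 5 of 22 lower (8 lower and 1 higher alone, DSP -0.21, CLDN4 -0.28, median -0.0838, adjusted p = 0.00698). Basal epithelial markers had 2 of 5 lower (3 alone, EGFR -0.32, JAG1 -0.26, median -0.258, adjusted p = 0.0348) and DNA replication and S phase 2 of 40 lower (MCM4 -0.35, RRM2 -0.31, median -0.152, adjusted p = 0.0348). These 4 calls were lost with an estimated correlation (adjusted p = 0.115, 0.115, 0.423 and 0.643), and MCM4 turned to 0.02 in the TPM fit. The ATF4 amino acid response had 2 of 25 higher and 3 lower (median -0.0734, adjusted p = 0.098). Over all genes 751 passed (332 higher, 419 lower; edgeR), with a median absolute log2 of 0.317 and 97 at least 2-fold changed, 84 of them higher. The balance turned to 369 higher and 272 lower in a fit of the compared groups alone. Leaving out control R1881 replicate 1, control R1881 replicate 3 or siNFYA R1881 replicate 3 left 402, 462 and 456 calls.

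The interaction tested whether the siNFYA effect differed between R1881 and vehicle. The effect was lower in R1881 than in vehicle for the glutamine carrier SLC1A5 (log2 -0.44, adjusted p = 0.000386), the cystine carrier SLC7A11 (-0.52), the mTOR inhibitor DDIT4 (-0.48), the mitochondrial folate enzyme MTHFD2 (-0.42) and the tRNA exporter XPOT (-0.32). The effect was higher in R1881 for the transcriptional co-regulator CITED2 (0.49, adjusted p = 0.000163), glutamine synthetase GLUL (0.41, adjusted p = 0.000373), the glucuronosyltransferases UGT2B11 (0.98, adjusted p = 0.000476) and UGT2B15 (0.75), and ACSL3 (0.38). In the ATF4 amino acid response 12 of 25 genes had a lower and 1 a higher effect (18 and 1 alone, median -0.341, camera adjusted p = 3.47e-23, and 0.013 with an estimated correlation). In serine, glycine and one-carbon metabolism 4 of 19 had a lower effect (median -0.190, adjusted p = 4.21e-11 and 0.00986). Mitochondrially encoded mRNAs had a higher effect in 8 of 13 (median 0.354, adjusted p = 2.12e-25 and 0.0471), and androgen-repressed genes in 3 of 17, with 1 lower (median 0.118, adjusted p = 0.00607 and 0.0471). Purine and pyrimidine synthesis (median -0.0944, adjusted p = 0.00165 and 0.0471) and DNA replication and S phase (median -0.285, adjusted p = 1.18e-08 and 0.0471) also passed both tests. G2/M cell cycle (median -0.180, adjusted p = 1.29e-07), glycolysis (median -0.112, adjusted p = 0.000183), immediate early genes (median -0.159, adjusted p = 0.0266) and androgen-induced genes (median 0.0468, adjusted p = 0.0413) passed, but were lost at adjusted p = 0.0501, 0.175, 0.142 and 0.562 with an estimated correlation. Over all genes 91 passed (42 higher, 49 lower; edgeR), and the balance turned in several settings, among them 53 and 39 with size factors of DESeq2, 52 and 32 by library totals, and 74 and 32 without siNFYA vehicle replicate 3. Leaving out control vehicle replicate 2, control R1881 replicate 2 or 3, siNFYA vehicle replicate 2 or siNFYA R1881 replicate 1 or 3 gave 57, 43, 57, 49, 264 and 47 calls, and in the TPM fit UGT2B11 was the only call.

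**Figure D5:**
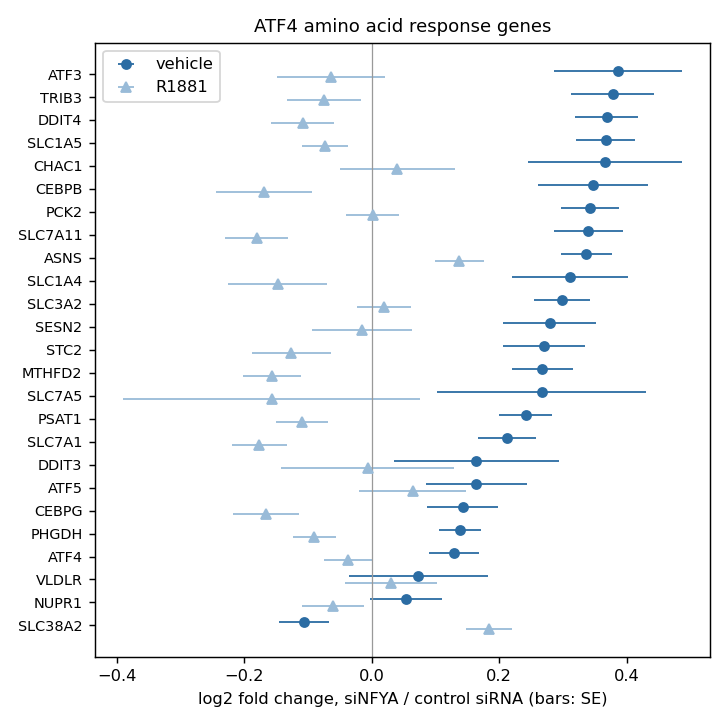
siNFYA log2 fold change (x axis, bars for the standard error) of the 25 measured genes of the ATF4 amino acid response (y axis) in vehicle (circles) and R1881 (triangles). The median is 0.271 in vehicle and -0.0734 in R1881.

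KLK3 and SEC62 were lower with siKLF5 in vehicle (n = 2 against n = 3), although KLF5 itself was not called there. KLK3 was alike in replicate 2 (33.3 CPM, scaled over all libraries) and replicate 3 (35.8), while KLF5 had 7 and 22 counts. With so few KLF5 counts, 2 libraries cannot show whether the KLK3 level follows KLF5. Whether either fall depends on KLF5 was not tested. KLK3 fell from 59.5 ± 5.50 to 34.5 ± 1.85 CPM (log2 -0.79, SE 0.0701, adjusted p = 6.59e-07) and the translocon subunit SEC62 from 151 ± 4.75 to 91.6 ± 5.62 CPM (-0.72, SE 0.0601, adjusted p = 2.86e-07). Falls were also called in ARHGEF35 (-0.76), HERPUD2 (-0.67) and the water channel AQP3 (-0.51). The largest rises were in the repair nuclease ERCC5 (1.47), RGPD5 (1.46), GOLGA8B (1.42), the readthrough JMJD7-PLA2G4B (1.40), PABPC1L (1.26) and NPIPB4. FKBP5 (-0.11, adjusted p = 0.521) did not pass, and TMPRSS2 (-0.23, adjusted p = 0.0414) lost its call in several settings. Of 7 lists that passed camera none passed with an estimated correlation (each adjusted p = 0.0796 unless given). Mitochondrially encoded mRNAs had 11 of 13 higher (13 alone, MT-CO1 0.53, MT-ND4 0.53, MT-ATP6 0.50, median 0.500, adjusted p = 4.60e-29), and cytosolic ribosomal proteins 10 of 73 lower (47 alone, RPS27 -0.24, RPS10 -0.23, RPL7 -0.20, median -0.121, adjusted p = 8.89e-40). Oxidative phosphorylation had 1 of 52 lower (5 alone, NDUFA4 -0.18, lost in several settings, median -0.107, adjusted p = 5.27e-12) and the tricarboxylic acid cycle 1 of 28 lower (DLD -0.18, median -0.0465, adjusted p = 0.00895). Androgen-induced genes had 5 of 74 lower (9 lower and 1 higher alone, PLPP1 -0.31, ACPP -0.30, median -0.0664, adjusted p = 0.00095), and the ATF4 amino acid response 3 of 25 higher (SLC7A1 0.23, SLC1A5 0.23, SLC7A11 0.26, median 0.0658, adjusted p = 0.00155, then 0.326). Glycolysis had 1 of 25 lower (LDHB -0.16, median -0.0392, adjusted p = 0.0253, then 0.326). Over 12733 genes 168 passed (98 higher, 70 lower; edgeR), and the balance turned in several settings. Among them were 79 and 89 without mitochondrial and rRNA-like genes and 190 and 219 with no filter. The DESeq2 Wald test gave 29 and 53, but only 2118 genes had an adjusted p there. Leaving out control vehicle replicate 2 or 3 left 75 and 74 calls, and leaving out siKLF5 vehicle replicate 2 or 3 gave 434 and 70, and SEC62 lost its call in the TPM fit.

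siKLF5 in R1881 lowered KLF5 and, as a list, endoplasmic reticulum stress and chaperones. SEC62 fell from 206 ± 5.86 to 126 ± 9.68 CPM (n = 3 each; log2 -0.71, SE 0.0537, adjusted p = 2.71e-08), HERPUD2, of the ubiquitin-like ER family, with -0.56, the membrane protein BRI3BP with -0.52, the ion-transport regulator FXYD3 with -0.50 and the disulfide isomerase AGR2 with -0.48. ODC1 fell from 4218 ± 93.2 to 3500 ± 135 CPM (-0.27, adjusted p = 3.57e-05) and the stearoyl-CoA desaturase SCD with -0.19 (adjusted p = 0.000769). The largest rises were in GOLGA8B (1.60), PABPC1L (1.40), GOLGA8A (1.38), NPIPB4 (1.30), the heat shock factor HSF4 (1.22) and the protocadherin PCDHGA5 (1.20). KLK3 was lower (-0.16, SE 0.0344, adjusted p = 0.0185; 3314 ± 50.8 against 3697 ± 70.7 CPM), a call lost when any 1 library was left out and in the TPM fit. TMPRSS2 (-0.07, adjusted p = 0.405) and FKBP5 (-0.02, adjusted p = 0.915) did not pass. Endoplasmic reticulum stress and chaperones had 5 of 27 lower (9 alone, PDIA6 -0.22, PDIA3 -0.15, HSPA5 -0.15, median -0.097, camera adjusted p = 1.63e-12, and 0.00279 with an estimated correlation). Hexosamine pathway and glycosylation had 2 of 15 lower and 1 higher (7 and 1 alone, GALNT7 -0.31, ST6GALNAC1 -0.25, OGT 0.38, median -0.110, adjusted p = 8.79e-06 and 0.0178), and cholesterol synthesis 1 of 24 lower (3 alone, HMGCS1 -0.16, median -0.0653, adjusted p = 2.70e-05 and 0.0265). Mitochondrially encoded mRNAs had 13 of 13 higher (MT-ATP6 0.86, MT-CO3 0.86, MT-CO1 0.85, median 0.856, adjusted p = 2.74e-52 and 0.0239).

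Further lists passed for siKLF5 in R1881 with the preset correlation alone. Androgen-induced genes had 7 of 74 lower and 4 higher (13 and 6 alone, ACPP -0.33, LMAN1 -0.18 against F5 0.46, median -0.0303; adjusted p = 0.00495, then 0.114 with an estimated correlation), and fatty acid synthesis and desaturation 3 of 25 lower (6 lower and 1 higher alone, FADS2 -0.23, ACSL1 -0.21, median -0.0335, adjusted p = 0.00159, then 0.114). Polyamine metabolism had 1 of 12 lower (median -0.0443, adjusted p = 0.0042, then 0.158) and androgen-repressed genes 1 of 17 higher (2 alone, IGFBP3 0.52, median 0.0529, adjusted p = 0.0411, then 0.203). No member passed over all genes in luminal epithelial markers (4 lower alone, median -0.0748, adjusted p = 0.000914, then 0.0802), G2/M cell cycle (1 higher alone, median 0.136, adjusted p = 1.86e-05, then 0.158), cytosolic ribosomal proteins (median -0.0382, adjusted p = 0.000309, then 0.543), glycolysis (median -0.0497, adjusted p = 0.0118, then 0.384) or the tricarboxylic acid cycle (median -0.0387, adjusted p = 0.0126, then 0.195). Over all genes 176 passed (106 higher, 70 lower; edgeR), with a median absolute log2 of 0.369. Each of the 6 left-out libraries moved this count more than 1.5-fold, to between 71 and 108.

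The siKLF5 interaction asked whether the siKLF5 effect differed between R1881 and vehicle, and KLK3 was its leading gene. The effect on KLK3 was less negative in R1881 than in vehicle (log2 0.63, SE 0.0783, adjusted p = 0.000752; 0.55 and adjusted p = 0.63 in the TPM fit). The readthrough ATP6V1G2-DDX39B also passed (0.86, SE 0.133, adjusted p = 0.012), and its call was lost when all libraries shared a fit (adjusted p = 0.507). These 2 genes were the only calls (854 at unadjusted p under 0.05; edgeR), against 2 in DESeq2 and 0 in limma on TPM. Leaving out control vehicle replicate 1, control R1881 replicate 3 or siKLF5 R1881 replicate 1 left KLK3 alone, and leaving out control R1881 replicate 2 or siKLF5 vehicle replicate 2 or 3 gave 6, 7 and 51 calls. The effect on endoplasmic reticulum stress and chaperones was lower in R1881 (median -0.0862, camera adjusted p = 9.68e-07, and 0.0232 with an estimated correlation). Cytosolic ribosomal proteins (median 0.0865, adjusted p = 9.66e-18), mitochondrially encoded mRNAs (13 of 13 higher alone, median 0.361, adjusted p = 3.20e-16), oxidative phosphorylation (median 0.0944, adjusted p = 7.21e-07) and G2/M cell cycle (median 0.140, adjusted p = 2.21e-05) passed, and were lost at adjusted p = 0.286 with an estimated correlation. So were the ATF4 amino acid response (median -0.0664, adjusted p = 0.0325, then 0.59) and fatty acid synthesis and desaturation (median -0.0351, adjusted p = 0.0366, then 0.323).

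siNFYA and siKLF5 shared part of their changes, and KLK3 set them apart. Of the genes higher with siKLF5 in vehicle, 83 of 97 were also higher with siNFYA. GOLGA8B and the mitochondrially encoded MT-CO1 were among genes higher in both. Of those lower in vehicle 24 of 70 were shared, in R1881 79 of 105 higher and 11 of 69 lower, while 3 genes in each treatment were called in opposite directions. Named after their values were seen, these were KLK3, MYNN and TBRG1 in vehicle, and in R1881 KLK3, TCAF1 and ODC1, the polyamine enzyme, at 0.18 with siNFYA and -0.27 with siKLF5. Both siRNAs were compared with the same control libraries, which by themselves make fold changes go together. Over 12554 genes the log2 fold changes had r = 0.4862 in vehicle and 0.5812 in R1881, where simulated unchanged groups against the same controls had 0.435 and 0.4895 on average and at most 0.4886 and 0.5384. With 1 control library for an siRNA and the remaining controls for the other, chosen after seeing the data, r ranged over 6 assignments from 0.0763 to 0.133 in vehicle and from 0.143 to 0.224 in R1881, against at most 0.0577 and 0.0703 in simulated unchanged groups. The simulations drew each gene separately, so their range leaves out variation that genes share between libraries. The numbers of shared calls were not tested against a count that allows for the common controls. Leaving out control vehicle replicate 2 or 3 or siKLF5 vehicle replicate 3 left 44, 42 and 25 shared higher genes in vehicle, and leaving out control R1881 replicate 1, 2 or 3 or siKLF5 R1881 replicate 1 or 2 left 38, 51, 46, 37 and 49 in R1881. Shared lower genes ranged from 7 to 33 in vehicle and from 1 to 11 in R1881 as each library was left out. Compared directly, a test chosen after seeing the data, KLK3 was higher with siNFYA than with siKLF5 in vehicle (log2 1.42, SE 0.0803, adjusted p = 1.20e-11) and in R1881 (0.34, SE 0.0466, adjusted p = 6.46e-05). This direct comparison called 774 genes in vehicle (304 higher, 470 lower) and 494 in R1881 (193 higher, 301 lower).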

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

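Genes and lists appear here because a test of the interaction found that the knockdown effect differed between R1881 and vehicle, and 4 group values because a class of transcripts outside the gene comparisons stood above its control level. Tests chosen only after the result was seen were the comparison of the mitochondrial list with all genes, the within-group trend, the rise of the retained-intron share by treatment and the comparison of siNFYA with siKLF5 for the ATF4 list, and the comparison with no control library in common.

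The siNFYA effect was higher in R1881 for CITED2 (log2 0.49), GLUL (0.41), UGT2B11 (0.98), UGT2B15 (0.75) and ACSL3 (0.38), and lower for SLC1A5 (-0.44), SLC7A11 (-0.52), DDIT4 (-0.48), MTHFD2 (-0.42) and XPOT (-0.32). Among lists it was lower for the ATF4 amino acid response (median -0.341), DNA replication and S phase (-0.285), serine, glycine and one-carbon metabolism (-0.190) and purine and pyrimidine synthesis (-0.0944), and higher for mitochondrially encoded mRNAs (0.354) and androgen-repressed genes (0.118). With the preset correlation alone, and lost with an estimated one, it was lower for G2/M cell cycle (-0.180, adjusted p then 0.0501), immediate early genes (-0.159, 0.142) and glycolysis (-0.112, 0.175), and higher for androgen-induced genes (0.0468, 0.562). The siKLF5 effect was higher in R1881 for KLK3 (0.63) and ATP6V1G2-DDX39B (0.86), and by list it was lower for endoplasmic reticulum stress and chaperones (-0.0862). With the preset correlation alone, and lost with an estimated one, it was higher for mitochondrially encoded mRNAs (0.361), G2/M cell cycle (0.140), oxidative phosphorylation (0.0944) and cytosolic ribosomal proteins (0.0865; adjusted p then 0.286 each), and lower for the ATF4 amino acid response (-0.0664, 0.59) and fatty acid synthesis and desaturation (-0.0351, 0.323). The share of counts on retained-intron transcripts was 2.87% with siNFYA in vehicle, 2.62% with siNFYA in R1881, 2.59% with siKLF5 in vehicle and 2.34% with siKLF5 in R1881, against 2.18 and 1.96% in the control groups.

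Mitochondrially encoded mRNAs were higher with both siRNAs in both treatments, although for siKLF5 in vehicle the list lost its call with an estimated correlation (adjusted p = 0.0796). The tables argue against scaling as the cause, since a factor per library moves all genes alike, and the list median exceeded the median of all genes by at least 0.506 in the 4 comparisons. Reads shared with 430 nuclear copies of mitochondrial genes stay open: their sum also rose, with a lowest log2 ratio of 0.435 (SE 0.197), and the bound set beforehand, that a rise would count against sharing, was wrong because reads coming from the copies would raise both. A trend in RNA make-up that also varies between libraries of a group had the values it needs, since mitochondrial and retained-intron shares went together within groups (r 0.804, exact permutation p = 0.0027, 17 libraries). The siRNA arm cannot be told apart from the preparation of its libraries, because the labels give no batch that crosses the arms, and an effect of the siRNAs on mitochondrial transcripts stays open too.

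The ATF4 amino acid response rose with siNFYA in vehicle and not in R1881. The tables argue against a single library as the cause, since the interaction median stayed at or below -0.3003 without any 1 library (lowest -0.3725). A make-up trend stays open. The retained-intron share rose with siNFYA by 0.655 points in R1881 (SE 0.0322) and 0.689 in vehicle (SE 0.119). The rise in R1881 was above 50% of that in vehicle by 0.310 points (SE 0.0675), yet the ATF4 medians were -0.0734 and 0.271. These values argue only against a trend that moves the list in step with that share in both treatments. How the list follows library make-up was not tested. With siKLF5 the list median was also higher in vehicle (0.0658) than in R1881 (0.0162), while the retained-intron share rose by 0.413 and 0.377 points. For siNFYA against siKLF5 in vehicle the ATF4 list median was 0.166 (camera adjusted p = 3.05e-07, and 0.109 with an estimated correlation). This comparison decides little, because the retained-intron share was higher with siKLF5 by less (0.413 points). No biological explanation was tested, and a difference in culture or preparation between the siNFYA vehicle libraries and the others stays open.

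siKLF5 and siNFYA fold changes went together over 12554 genes. The covariance was 0.04002 in vehicle and 0.06139 in R1881, above the highest of 20 simulations with the same controls (0.02333 and 0.03127). The correlation in vehicle lay within the simulated range (0.4862, highest 0.4886). With no control library in common the lowest covariance of 6 assignments was 0.01073 in vehicle and 0.02498 in R1881, against at most 0.004723 and 0.006822 in simulated unchanged groups. Every assignment was thus above 0 without a common control. The simulations drew each gene separately and leave out variation that genes share between libraries, so their range cannot decide whether shared controls and such variation are enough. Shared controls add to the covariance, as the simulations with the same controls had a mean of 0.0192 in vehicle and 0.02697 in R1881. A response common to both siRNA pools and not the control siRNA, or preparation by arm, may add to it, and no libraries of the design part these.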

How the results depend on the processing

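Chosen only after seeing the data were scaling by library totals and removal of mitochondrial and rRNA-like genes. R1881 against vehicle in control siRNA stayed within 1.5 times its count in every alternative run. Knockdown of NFYA kept its direction and call throughout.

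With the DESeq2 Wald test calls were 956 (siNFYA vehicle), 397 (siNFYA R1881), 82 (siKLF5 vehicle) and 105 (siKLF5 R1881). For siKLF5 in vehicle only 2118 genes had an adjusted p in that test, against 12733 in edgeR. With no filter they were 326 (siNFYA interaction with R1881), 409 and 388 (siKLF5 vehicle and R1881) and 106 (siKLF5 interaction with R1881), and KLF5 in vehicle passed (log2 -1.09). A fit of only the groups of the comparison gave 81 for siKLF5 in vehicle and 314 in R1881. At adjusted p under 0.01 calls were 808, 319 and 30 for siNFYA (vehicle, R1881, interaction) and 51, 70 and 1 for siKLF5. With limma-trend on log2(TPM + 1) they were 457, 194 and 1 for siNFYA and 2, 36 and 0 for siKLF5, where edgeR had 2 and an unadjusted p under 0.05 was met by 854 genes in edgeR. With all libraries in 1 fit the siNFYA interaction had 59, siKLF5 in vehicle 108 and the siKLF5 interaction 1. The cause was not tested, except that in TPM 1 estimated count on a short transcript of KLF5 carried 35.5 of 40.1 TPM in siKLF5 R1881 replicate 2, so that KLF5 in R1881 came to -0.14 there (adjusted p 0.949).

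Shared calls of siKLF5 and siNFYA (vehicle higher and lower, R1881 higher and lower) were 134, 67, 137 and 48 with no filter, and 34, 3, 31 and 2 at adjusted p under 0.01. Camera with an estimated correlation left 4, 1 and 6 lists for siNFYA (vehicle, R1881, interaction), 0, 4 and 1 for siKLF5, and 8 for R1881 in siKLF5. Without mitochondrial and rRNA-like genes 2 lists passed for siNFYA in R1881.

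Of 231 values of named genes, size factors of DESeq2 kept all on their side of the threshold, the TPM fit lost 98 and turned 3, library totals lost 4 and turned 1, adjusted p under 0.01 lost 43, and a single fit lost 11. The turned values were RPL34 in R1881 against vehicle in control siRNA (-0.0227 in TPM, -0.0948 by library totals), TMPRSS2 in siNFYA against control siRNA, vehicle (0.103 in TPM) and MCM4 in siNFYA against control siRNA, R1881 (0.0235 in TPM). Library totals put the median of all genes for R1881 at -0.247, -0.242 and -0.240 (control, siNFYA, siKLF5), from -0.0102, -0.0183 and -0.00593, and took the share to 28.21, 28.15 and 28% of calls higher from 51.07, 50.15 and 51.92%, since R1881 libraries have lower TMM factors. The TPM fit gave 37.25, 34.67 and 34.21%. The siNFYA interaction had 46.15% of calls higher, 57.61% with size factors of DESeq2 and 61.90% by library totals. For siKLF5 in vehicle the share was 58.33%, 47.02% without mitochondrial and rRNA-like genes and 75.31% in a fit of only the groups of the comparison. It was 35.37% with the DESeq2 Wald test, over 2118 genes. siNFYA in vehicle had 49.59% higher, and 42.72% with size factors of DESeq2. siNFYA in R1881 had 44.21% of calls higher, 57.57% in a fit of only the groups of the comparison and 37.12% without mitochondrial and rRNA-like genes.

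Leaving out each library in turn gave 1065 to 1604 calls for siNFYA in vehicle, 402 to 674 in R1881 and 43 to 264 for its interaction, and 70 to 434, 71 to 108 and 1 to 51 for siKLF5. The lowest and highest came without control vehicle 2 and siNFYA vehicle 3, control R1881 1 and siNFYA R1881 1, control R1881 2 and siNFYA R1881 1, siKLF5 vehicle 3 and 2, siKLF5 R1881 1 and 3, and control vehicle 1 and siKLF5 vehicle 3. Lists for siNFYA in R1881 ran from 3 to 7, KLF5 in vehicle from -2.14 to -0.46, and shared calls from 25 to 99, 7 to 33, 37 to 73 and 1 to 11. Of 1426 values of named genes 187 lost their call and none turned. Without a siKLF5 vehicle library that arm has 1 sample, which is assumed to vary like the other groups. The alternative that keeps library 7 was not run, as the tables used hold no column of it.

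At this depth 3 replicates recovered 66% of 1.5-fold changes in simulated data for siNFYA in vehicle, so smaller changes of single genes are partly missed.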

Other observations

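Splits balanced over the arms, the within-group trend of the mitochondrial and retained-intron shares and the direct comparison of the arms were chosen only after the results were seen. The genes GOLGA8A, GOLGA8B and PABPC1L rose with both siRNAs, in the same libraries in which mitochondrial and retained-intron shares were higher. Averaged over treatments, the mitochondrial share was higher with siNFYA by 1.06 points and the retained-intron share by 0.672. With siKLF5 they were higher by 0.969 and 0.395 (exact permutation p = 0.005 each, the smallest these arrangements give). Whether these genes follow the make-up trend within groups was not tested. The exact permutation p = 0.0027 of that trend is for the mitochondrial and retained-intron shares alone.

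Other splits of the samples were counted for each comparison of 3 with 3 libraries. The real split alone, 1 of 10, had as many calls for R1881 in control siRNA (7932, highest other 0), siNFYA in vehicle (1696, highest other 1), siNFYA in R1881 (751, highest other 1), siKLF5 in R1881 (176, highest other 2) and R1881 in siNFYA (7828, highest other 0), and 10 splits are too few for a share under 0.05. Every other split also mixes libraries of both groups, which widens the spread within groups where the groups differ. The low counts of those splits therefore decide nothing. For the siNFYA interaction 5 of 100 splits had at least as many calls as the real 91 (highest other 319), so chance is not excluded by them. Splits that call several times the real count point to a structure of the samples, since a split that trades arms within a treatment turns the arm difference into an interaction. Among 82 splits balanced over the arms 1, the real split, had as many (highest other 1). These decide nothing, because they mix siNFYA with control libraries in each group: the lowest common dispersion of the others was 0.00411 against 0.00155, so calls are lost whether or not the interaction is real.

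KLK3 moved in opposite directions in vehicle, higher with siNFYA and lower with siKLF5, and KLF5 itself was 1 of the genes that R1881 raised. Of 17 androgen-repressed genes 8 were lower and 1 higher with siNFYA than with control siRNA in vehicle, where no R1881 was given. Androgen-induced genes did not rise as a list in that comparison, with 14 of 74 lower and 4 higher (median log2 -0.0957). Their camera adjusted p was 0.00327, and 0.333 with an estimated correlation. The library labelled siKLF5 vehicle replicate 3 had 22 counts of KLF5, as many as a control library, and without it KLF5 in vehicle was at -2.14.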
